A study of Gallus gallus with 8 samples.

How the data were processed

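RNA was measured in 8 libraries of primary chicken skin cells: fibroblasts at confluence (1 library), keratinocytes before confluence (1 library), keratinocytes grown to a confluent monolayer (3 libraries) and keratinocytes differentiated in a skin equivalent, a layered culture in 3 dimensions (3 libraries). Per the labels, RNA was isolated with Trizol, libraries were made with a poly(A) selection and a strand-preserving kit, and paired reads of 75 bases were sequenced on a NextSeq500. The titles of replicates 1, 2 and 3 carry the codes 20, 34 and 56 in both replicated groups, and that of the subconfluent library carries 20. A number marked d is 8 in the confluent monolayers and 7 in skin equivalent 1, and the other titles have none. The letters wo stand in the titles of replicates 2 and 3 of both replicated groups and in no other title. What the codes, this number and this mark stand for is not given in the sources used here. The labels do not say whether libraries of a group came from separate birds or cultures, so p-values measure the spread between these libraries, which may be technical.

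The deposited files hold whole-number counts per feature, without normalisation, made by the authors, with 24902 features and 4 further rows for fragments given to no gene. The submitters' processing notes name bcl2fastq 2.19.1.403, STAR 2.6.1a, RSEM and DESeq2 1.22.2, without a role for each. The 4 further rows carry the names that STAR gives to unmapped, multimapping, unassigned and ambiguous fragments, and the values are whole, so they were treated as counts and not as RSEM estimates, for which the plan had allowed rounding. The genome build, the gene annotation and the strand setting of the counting are not given in the sources used here, so no coordinates are printed. Counting of this kind leaves out fragments that map to several places, so members of multigene families such as keratins and corneous beta-proteins are uncertain, and so are overlapping and antisense genes.

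Of the features, 24759 carry an ENSGALG identifier and 143 carry a name set by the authors. The reference gene table at hand, of assembly GRCg7b, pairs 0 of its genes with an Ensembl identifier, so identifiers were not turned into names. Fixed lists of gene symbols, 26 in number and written before the data were examined together with the tests, the named-gene rule and most alternatives, were matched to the deposited names without regard to case or suffix. Only 3 lists had a matched member and only 2 had at least 5. These were the keratins (10 members, from 25 symbols) and the epidermal differentiation complex (21 members, from 41 symbols). The Krt5L, Krt14L, Krt9L and Krt78L names matched no symbol of the keratin list. The basal layer list had 1 member, Krt15, and the other lists, on other cell types, the cell cycle, lipids, defence and further subjects, had 0 and were not analysed here. Families of names were defined after names and counts had been seen, from the starts Krt, Krt9L and Krt78L and the endings -EDC and, for corneous beta-proteins (CBP), -C, -F, -K and -S. The files do not spell out these endings.

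The rows of no gene stayed out of library sizes and tests. Between 64.5% and 71.3% of a library's fragments were given to a gene, unassigned fragments made up 13.7% to 22.2%, multimapping ones 3.26% to 8.66%, unmapped ones 3.77% to 9.22% and ambiguous ones 0.485% to 2.53%. Gene counts ranged from 27329706 to 36728801 per library. A floor of 3 counts corresponded to 0.0807 to 0.117 CPM (normalised counts scaled to a common library size), and ratios against groups at 0 counts are lower bounds against that floor per library. Ratio intervals are 95% counting intervals. Intervals and floors cover counting error only, since reads carry no molecular identifiers.

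Each comparison used the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 with robust dispersion, TMM scaling, its default expression filter and Benjamini-Hochberg adjustment at 0.05. Skin equivalents and confluent monolayers were compared in a fit of those 6 libraries. Fibroblasts and subconfluent keratinocytes, with 1 library each, were compared with the monolayers in a fit of all 8 libraries, which assumes that a lone library varies like the replicated groups and gives no replicate check. Errors of log2 fold changes are standard errors derived from the fold and the test statistic. CPM values were scaled over all 8 libraries, so they can differ slightly from folds of the fit of 6. Lists of at least 5 tested members were tested with camera in limma 3.58.1 at a preset correlation of 0.01. Shares of counts were compared by a two-sided exact permutation test, whose smallest p with 3 against 3 libraries is 0.1.

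Named features follow a rule: the 6 largest rises and 6 largest falls among named features past the threshold with a mean log2 CPM of at least 3 (and, for skin equivalents, no overlap between groups), the 2 largest changes of each list, and Krt15, CRNN and SCFN in any case. Other genes that the rule always names, such as TP63 and MKI67, had no matching name and were not analysed here. Further features were chosen after their values were seen: the 3 most abundant of each family and a hand-picked set. That set was shortened once after the alternatives had been seen, which removed features whose sign reversed, and was then restored in full, so that features whose sign moved are reported.

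The method was tested on simulated counts with 200 changed features. With changes of 2- and 4-fold, the comparison of skin equivalents (13230 features) recovered 7% of the 2-fold and 75% of the 4-fold changes with 13 false calls. The comparison of fibroblasts (15019 features) recovered 0% and 5%, and that of subconfluent cells (15019 features) 0% and 8%. A second simulation, with 16- and 64-fold changes added, was made after these low shares were seen. There the 4-fold changes were recovered at 74%, 34% and 32% in the same order, and 64-fold changes at 100%, 92% and 96%. In both simulations the single-library comparisons missed most changes of 2- to 4-fold.

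Alternatives were DESeq2 1.42.0, limma-voom, other scalings and filters, a fold threshold, other libraries in the fit, the replicate number as a block, leaving out each replicated library, and for lists an estimated correlation and fry. Name families and shares, with their alternatives, lower bounds without each library, and fits with the title mark wo as a term or of only the libraries that carry it were added after the data were seen.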

Results

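Gene expression was compared between chicken skin cells grown as monolayers and as skin equivalents. The data comprised 3 skin equivalents and 3 confluent keratinocyte monolayers, 1 library of subconfluent keratinocytes and 1 library of confluent fibroblasts. Gene counts were 27940842, 30062632 and 30533216 in monolayers 1 to 3 and 28792451, 27329706 and 27815090 in skin equivalents 1 to 3. The subconfluent library held 36728801 and the fibroblast library 28767054. Values with an error are means ± SD over 3 libraries for CPM and shares, and estimates ± standard error for log2 fold changes. Features are named as in the count tables, and adjusted p-values of features are from the edgeR quasi-likelihood test.

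The first comparison asked how the transcriptome of keratinocytes in skin equivalents differed from that in confluent monolayers. Keratins, the filament proteins of epithelial cells, took up 11.5% ± 2.09 of gene counts in skin equivalents and 2.00% ± 0.389 in monolayers. Features of the Krt9L and Krt78L families made up most of the difference, with 4.79% ± 0.977 and 4.36% ± 0.832 in skin equivalents against 0.0176% ± 0.00262 and 0.0415% ± 0.0281 in monolayers. Krt7, Krt18 and Krt19, keratins known from simple epithelia, fell. Features of the epidermal differentiation complex, a gene cluster that encodes proteins of the cornified layer, and corneous beta-proteins, the structural proteins of hard skin appendages in birds and reptiles, rose in most cases.

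Among keratins, Krt9L3 was the most abundant in skin equivalents, at 38733 ± 7124 CPM against 6.99 ± 4.07 in monolayers (log2 fold change 12.44 ± 0.80, adjusted p = 8.78e-05). Krt9L4 rose from 0.258 ± 0.140 to 2695 ± 527 CPM, and the 7 tested Krt9L features all rose. Of 6 tested Krt78L features, 3 rose and 1 fell. Krt78L3 (24618 ± 3898 CPM, from 28.0 ± 18.4) and Krt78L2 (21745 ± 5797 CPM, from 30.9 ± 20.2) rose, whereas Krt78L1 fell by 3.28 ± 0.76 on the log2 scale (log2 fold change -3.88 without monolayer 1). Krt78L4 had a log2 fold change of 3.28 ± 1.29 and did not pass the test (adjusted p = 0.0688). Skin equivalent 2 carried this value: the CPM were 35.0, 1284 and 122 in skin equivalents 1 to 3, and the log2 fold change was 0.66 without skin equivalent 2. Krt78L4 was called without skin equivalent 1 (3.84, adjusted p = 0.0299) and with DESeq2 (3.16, adjusted p = 0.0327). Members of the Krt5L names moved in opposite directions: Krt5L1 rose to 15373 ± 3274 CPM from 2032 ± 1038 (log2 fold change 2.93 ± 0.49), while Krt5L3 fell by 5.83 ± 1.2 and Krt5L2 by 2.92 ± 0.86. Without skin equivalent 2 their log2 fold changes were -8.26 and -4.33. The call of Krt5L2 was lost without monolayer 1 (adjusted p = 0.0501) and without skin equivalent 1 (adjusted p = 0.0859), and in the fit of only the libraries with wo in their titles (adjusted p = 0.121). Krt14L1 rose by 1.43 ± 0.24 on the log2 scale. Krt14L2 had a log2 fold change of 0.21 ± 0.31 (adjusted p = 0.60), whose sign turned negative with scaling by total count, without monolayer 1 and without skin equivalent 2. Over all keratin names, 13 of 29 tested features rose and 10 fell, and the family as a whole did not pass the camera test (adjusted p = 0.311).

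**Figure D1:**
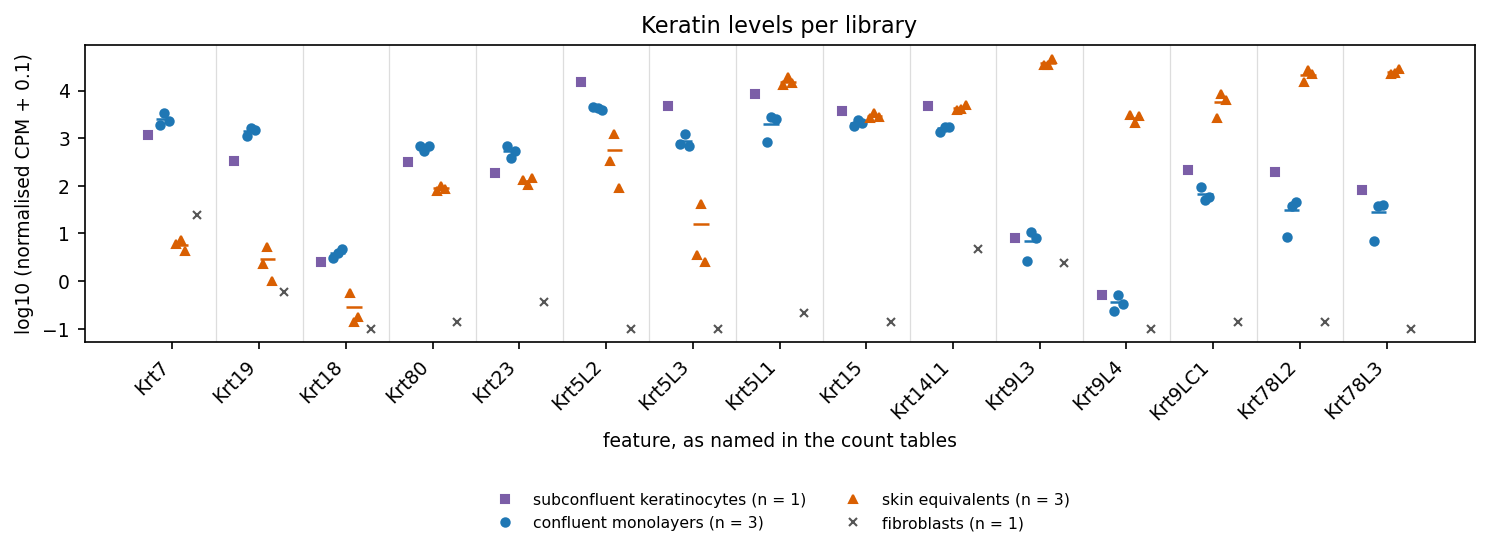
Levels of 15 keratin features in each library, as log10 of normalised CPM plus 0.1 (vertical axis) by feature (horizontal axis), with 1 symbol per library and a bar at the mean of the groups with n = 3. Krt9L3 lay at 38733 ± 7124 CPM in skin equivalents and 6.99 ± 4.07 CPM in confluent monolayers, and Krt7 at 5.72 ± 1.45 and 2529.9 ± 729 CPM.

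Of 25 established symbols in the fixed keratin list, 10 matched a deposited name. The Krt5L, Krt14L, Krt9L and Krt78L names lie outside it, so it does not stand for keratins as a class. The matched members moved down as a group (camera adjusted p = 0.00514). The list was not past the threshold once the correlation was estimated from the data (adjusted p = 0.0864 with an estimated correlation). Over all features 1 member rose and 6 fell, and adjusted over the list alone 1 rose and 7 fell. Krt19 fell by 8.99 ± 0.76 on the log2 scale, from 1419.7 ± 271 to 2.78 ± 2.2 CPM (adjusted p = 2.10e-04), with a log2 fold change of -9.81 without skin equivalent 2. Krt7 fell by 8.78 ± 0.43, from 2529.9 ± 729 to 5.72 ± 1.45 CPM (adjusted p = 4.14e-05). Falls of Krt18 (4.28 ± 0.79 lower on the log2 scale, at 3.82 ± 0.870 CPM in monolayers), Krt80, Krt20 and Krt23 also passed the test, with log2 fold changes of -2.86, -2.12 and -2.08 for the last 3. Without skin equivalent 1 the log2 fold change of Krt18 was -5.94. Krt12 was the member that rose, with a log2 fold change of 2.39 ± 0.79 at 1.26 ± 0.998 CPM (adjusted p = 0.0399), and this call was lost without any one of monolayers 1, 2 and 3 or skin equivalents 2 and 3 (adjusted p = 0.0614, 0.120, 0.126, 0.0744 and 0.142), with a log2 fold change of 1.67 without skin equivalent 3. It was lost too with the title mark wo as a term (adjusted p = 0.0877). Krt15, a basal-layer keratin and the only matched member of the basal layer list, had 2972 ± 397 CPM in skin equivalents and 2092 ± 284 in monolayers (log2 fold change 0.51 ± 0.24, adjusted p = 0.119). Krt8 had a log2 fold change of -0.93 ± 0.36 (adjusted p = 0.0674), and was called as lower without monolayer 1 (adjusted p = 0.00338), among only the libraries with that mark (0.00521), with DESeq2 (0.0235) and with total counts (0.0337).

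In the fixed list of the epidermal differentiation complex, 14 of 16 tested members rose and 1 fell, both over all features and adjusted over the list alone. Some members, such as LOR1-EDC and LOR2-EDC with at most 4 counts in a monolayer, passed the filter through skin equivalents. Only a rise could be called for these. The list was called by camera (adjusted p = 9.09e-07), but not with the correlation estimated (adjusted p = 0.121 with an estimated correlation). LOR1-EDC, named after loricrin, a main protein of the cornified envelope, rose from 0.101 ± 0.0133 to 982 ± 283 CPM (log2 fold change 13.19 ± 0.44, adjusted p = 1.84e-05), and LOR2-EDC rose by 12.87 ± 1.38 (11.24 without skin equivalent 1). EDQL-EDC was already at 359 ± 268 CPM in monolayers and rose to 4601 ± 2204 (log2 fold change 3.67 ± 0.68, or 4.37 without monolayer 1). EDPE-EDC rose by 2.83 ± 0.58, or by 3.52 without monolayer 2. CRNN-EDC, named after cornulin, was the member that fell (log2 fold change -2.17 ± 0.58, adjusted p = 0.0176). It was near the floor in skin equivalents, at 0.154 ± 0.0372 CPM, and its call was lost without skin equivalent 2 (adjusted p = 0.0573) and without skin equivalent 3 (adjusted p = 0.0601). SCFN-EDC had too few counts to be tested. Of all 27 tested names ending in -EDC, 24 rose and 1 fell.

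Corneous beta-proteins ending in -K rose in 14 of 15 cases, and those ending in -C in 14 of 14. For -S, 10 of 21 features had enough counts to be tested, and 10 rose. Monolayers 1 to 3 held only 35, 7 and 6 counts over all -C names and 79, 27 and 18 over all -S names. The tested -C and -S features thus passed the filter through skin equivalents, and only rises could be called among them. The same held for some -K features, such as CBP65-K and CBP16-K, which had 0 counts in the monolayers. With a stricter filter, of at least 50 counts in 3 libraries, 9 of the -K and 5 of the -S features were called. These were all the -K and -S features that this filter kept, so the others left the test. Of the 20 ending in -F, 2 were tested and 0 were called, with CBP17-F at 13.6 ± 2.68 CPM in skin equivalents and 8.26 ± 7.91 in monolayers (log2 fold change 0.72 ± 0.63, adjusted p = 0.375). CBP17-F was called as higher without monolayer 1 (log2 fold change 1.77) and among only the libraries with wo in their titles (1.89). CBP63-K reached 10090.0 ± 2899 CPM from 0.543 ± 0.402 (log2 fold change 14.17 ± 0.79), and CBP62-K 6358 ± 583 CPM from 0.367 ± 0.317 (log2 fold change 14.06 ± 0.76). Without monolayer 2 these were 14.94 and 15.03. CBP65-K had 203 ± 105 CPM in skin equivalents and 0 counts in the monolayers, which made it at least 2215-fold higher. CBP3-C, CBP9-C and CBP4-C were likewise at 0 counts in the monolayers and at least 779-fold, 670.1-fold and 587-fold higher. Skin equivalent 2 carried these bounds, which were 171-fold, 249-fold and 117-fold without it. The -S features differed widely among skin equivalents: CBP52-S had 688 ± 1081 CPM, and its call was lost with limma-voom (adjusted p = 0.0825), with a log2 fold change of 12.98 that became 9.55 without skin equivalent 2. The -S and -C features together held 0.0387%, 0.967% and 0.0867% of gene counts in skin equivalents 1, 2 and 3. In the fit without skin equivalent 2, the numbers of called members of each family stayed within 1.5 times of these.

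**Figure D2:**
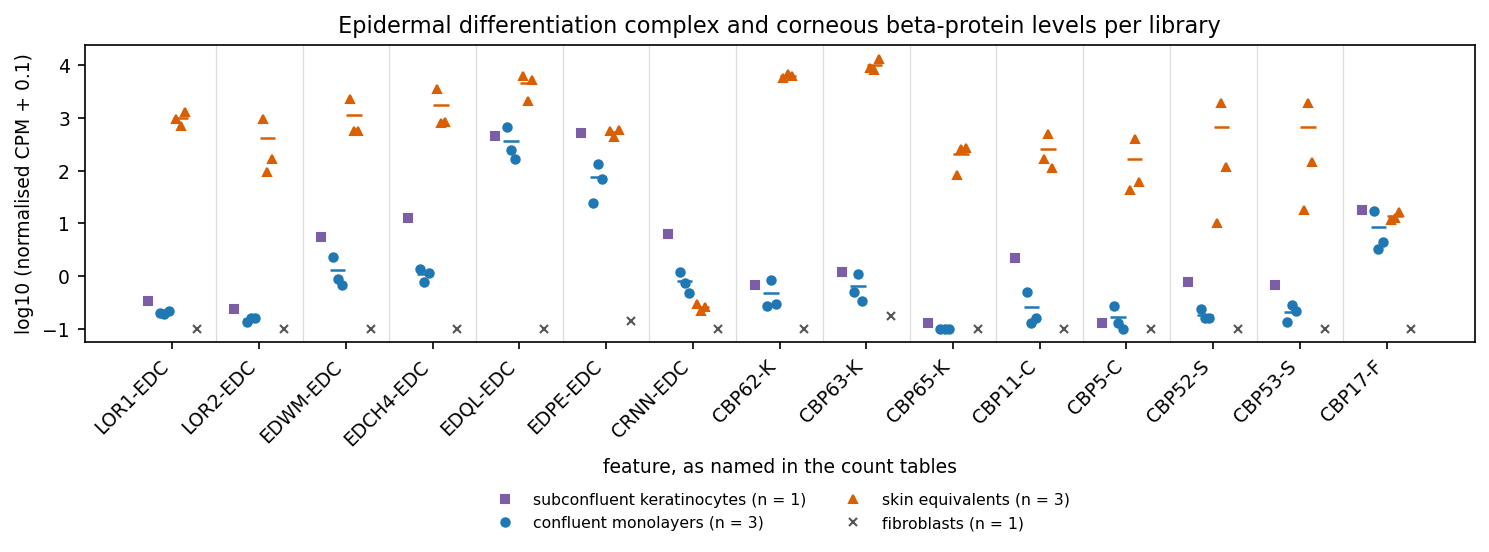
Levels of 15 features of the epidermal differentiation complex (-EDC) and of corneous beta-proteins (CBP) in each library, as log10 of normalised CPM plus 0.1 (vertical axis) by feature (horizontal axis), with 1 symbol per library and a bar at the mean of groups with n = 3. LOR1-EDC lay at 982 ± 283 CPM in skin equivalents and 0.101 ± 0.0133 CPM in monolayers, and the 3 skin equivalents were spread widely for CBP52-S (688 ± 1081 CPM).

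Camera called 5 of 7 tested name families, all upwards: -EDC (adjusted p = 1.94e-08), CBP -K (6.45e-06), Krt9L (1.75e-05), CBP -C (1.75e-05) and CBP -S (0.00451). Since the -C and -S features passed the filter through skin equivalents, the direction of the -C and -S calls was fixed in advance. Some -K and -EDC features, such as CBP65-K, CBP16-K, LOR2-EDC and EDYM1-EDC, also passed only through skin equivalents. The direction of the -K and -EDC calls was thus fixed in part. With an estimated correlation 0 were called, with adjusted p = 0.329, 0.329, 0.204, 0.421 and 0.421 with an estimated correlation in the same order. As shares of gene counts, -K names were higher in every skin equivalent than in every monolayer (1.87% ± 0.384 against 0.00469% ± 0.00207), and so did -EDC names (1.25% ± 0.706 against 0.0555% ± 0.0274). The two-sided exact permutation test gave p = 0.1 for both, for keratins and for each other family except -F (p = 0.5), and 0.1 is the smallest p that 3 against 3 libraries allow. Single features outside these families changed as well. EPPKL1 rose from 0.488 ± 0.172 to 496 ± 153 CPM (log2 fold change 9.98 ± 0.47), and IL36RN, named after an antagonist of interleukin-36 signalling, from 2.03 ± 2.28 to 275 ± 128 CPM (log2 fold change 7.09 ± 1.05, or 8.43 without monolayer 1).

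**Figure D3:**
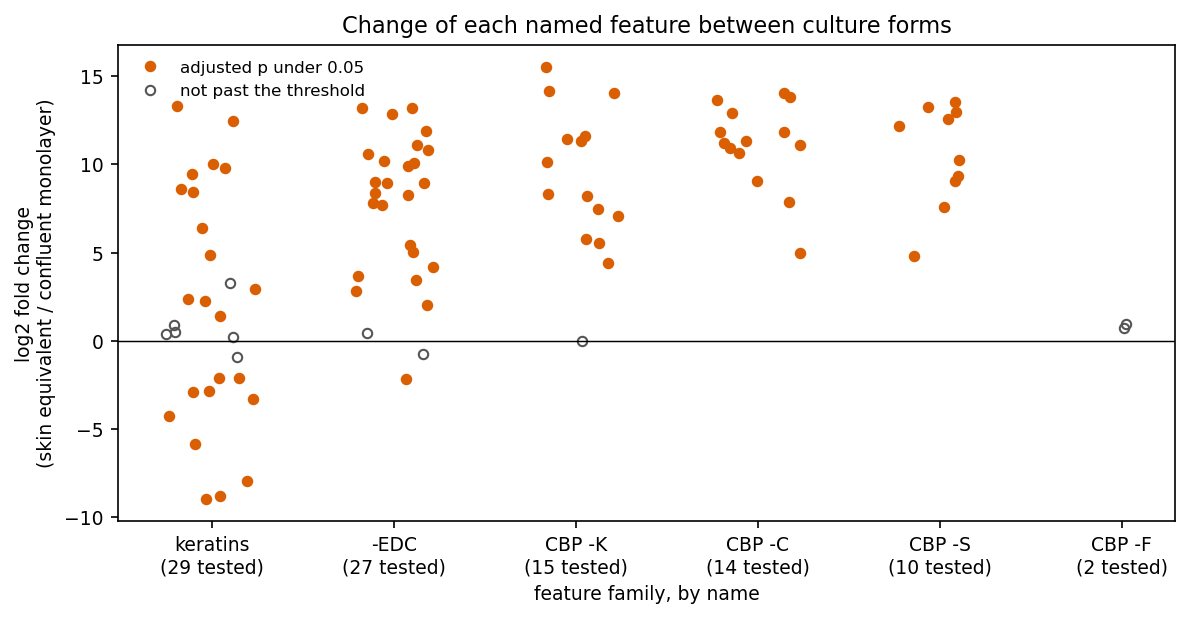
Log2 fold change of each tested named feature between skin equivalents and confluent monolayers (vertical axis, n = 3 against n = 3) by name family (horizontal axis), with filled points past the adjusted p threshold of 0.05 and open points not past it. Points are spread sideways for legibility, and fitted folds of features with 0 counts in a group depend on the prior count. Of 29 keratins 13 rose and 10 fell, and of 15 CBP features ending in -K 14 rose.

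Of 13230 features tested, 3427 rose and 3122 fell in skin equivalents, of which 2676 and 2597 by over 2-fold. Of the 102 named features tested, 79 rose, 11 fell and 12 were not called. Scaling by total count alone moved the median log2 fold change of all features from 0.08 to -0.18 and gave 2517 rises and 3918 falls. A number marked d in the sample titles was 8 in the monolayers, 7 in skin equivalent 1 and missing in skin equivalents 2 and 3, so whether time in culture differed between the groups is open. The titles of replicates 2 and 3 of both groups carry the mark wo, and those of replicate 1 do not. With this mark as a term in the fit 3714 features rose and 3310 fell, and among only the 4 marked libraries 3621 rose and 3881 fell. Among features without a name, ENSGALG00000010828 and ENSGALG00000008048 had 0 counts in the monolayers and 38.0 ± 21.1 and 20.7 ± 4.35 CPM in skin equivalents. ENSGALG00000000357 and ENSGALG00000016805 had 89.8 ± 53.3 and 29.6 ± 3.90 CPM in monolayers and 0 counts in skin equivalents.

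The second comparison set fibroblasts, the cells of the dermis, against confluent keratinocytes. Named keratins were nearly absent from the fibroblast library: all 32 together took 891 counts, or 0.00310% of gene counts, against 2.00% ± 0.389 in monolayers. Krt5L2, the most abundant keratin of the monolayers at 4257 ± 332 CPM, had 0 counts in fibroblasts and was at least 36721-fold lower, and Krt5L3 was at least 7698-fold lower. Krt15 had 1 count in fibroblasts and 2092 ± 284 CPM in monolayers, a 54129-fold ratio whose counting interval began at 9715. IL1RN, named after an antagonist of interleukin-1 signalling, was the single named feature that rose, at 10.6 CPM in fibroblasts against 0.493 ± 0.308 (log2 fold change 4.43 ± 0.62, adjusted p = 0.00192). It was also higher in skin equivalents than in monolayers, with log2 fold changes of 3.90 to 4.73 over single libraries left out. IL1RN thus did not set fibroblasts apart from keratinocytes in general.

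In the fixed keratin list 9 of 10 members fell, and 9 adjusted over the list alone. The list was called by camera (adjusted p = 2.85e-06) and held with the correlation estimated (adjusted p = 0.0146 with an estimated correlation). Krt8 had 0 counts in fibroblasts and was at least 1394-fold lower. Krt7 kept 618 counts (23.9 CPM) and Krt14L1 kept 117 counts (4.52 CPM) in fibroblasts, and both fell, by 6.73 ± 0.66 and 8.48 ± 0.58 on the log2 scale. In the list of the epidermal differentiation complex 4 of 19 members fell, 2 adjusted over the list alone, whereas 10 fell with DESeq2 and 9 with scaling by total count. Its camera call (adjusted p = 0.0262) was lost with the correlation estimated (adjusted p = 0.364 with an estimated correlation), with fry (adjusted p = 0.0988) and without monolayer 1 (adjusted p = 0.128). EDPE-EDC, CRNN-EDC and EDCH4-EDC were among those that fell, and the call of EDCH4-EDC was lost without monolayer 1 (adjusted p = 0.0791) and without monolayer 3 (adjusted p = 0.0632). EDQL-EDC, outside the fixed list, had 0 counts in fibroblasts and was at least 3099-fold lower (1779-fold without monolayer 1). SCFN-EDC had 0 counts in fibroblasts and 0.117 ± 0.178 CPM in monolayers (adjusted p = 0.343). In the list, LOR1-EDC, LOR2-EDC, EDQM3-EDC, EDMTF1-EDC and EDMTF3-EDC lay at or under the fibroblast floor of 0.116 CPM in fibroblasts and in the monolayer mean. So did EDGH-EDC and EDYM1-EDC among the other -EDC names, and a fall could hardly be seen in any of these. LOR1-EDC, at 0.101 ± 0.0133 CPM in monolayers, had an adjusted p of 0.0647. Of the name families, all keratins (25 of 31 fell, camera adjusted p = 1.17e-07) and -EDC (10 of 31 fell, camera adjusted p = 0.0199) were called, and neither held with the correlation estimated (adjusted p = 0.286 and 0.730 with an estimated correlation). The -EDC call was also lost without monolayer 1 (adjusted p = 0.120). The number of -EDC features that fell was 16 with DESeq2 and 5 with limma-voom. Corneous beta-proteins ending in -C, -F and -S had 0 counts in fibroblasts, where 3 counts correspond to 0.116 CPM, and those ending in -K had 2 counts. Monolayers 1 to 3 held only 35, 7 and 6 counts over all -C names and 79, 27 and 18 over all -S names. For -C and -S the absence from fibroblasts therefore says little about cell type.

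In all, 3228 of 15019 features rose and 3458 fell in fibroblasts, and 2641 rose and 4309 fell with scaling by total count, which moved the median log2 fold change from -0.18 to -0.49. ENSGALG00000004154 (1954 CPM in fibroblasts against 0.257 ± 0.0826) and ENSGALG00000011740 (1551 against 0.873 ± 1.11) rose. In this library 13.7% of fragments were unassigned, against 21.0% ± 1.47 in monolayers, and 2.53% were ambiguous, against 0.538% ± 0.0465. The strand setting of the counting is not given in the sources used here, so whether this library was counted like the others is open for every fibroblast value. With 1 fibroblast library the difference between cell types has no replicate check.

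The third comparison set subconfluent against confluent keratinocytes. CBP58-K (7.51 CPM against 0.19 ± 0.140, log2 fold change 5.31 ± 0.84, adjusted p = 0.0410) and EDCH3-EDC (8.07 CPM against 0.334 ± 0.177, log2 fold change 4.60 ± 0.67, adjusted p = 0.0390) rose in subconfluent cells, and no other named feature was called. Of the named features followed through the alternatives, a further 16 were called with DESeq2, 7 without monolayer 1 and 9 with the title mark wo as a term. Both calls were lost without monolayer 2 (adjusted p = 0.125 for CBP58-K and 0.116 for EDCH3-EDC) and without monolayer 3 (adjusted p = 0.182 and 0.173). They were also lost with only these groups in the fit (adjusted p = 0.0905 and 0.0816), with limma-voom (adjusted p = 0.0820 and 0.0543) and with the replicate number as a block. Keratins held 4.49% of gene counts in the subconfluent library against 2.00% ± 0.389, and Krt5L2 alone was at 15307 CPM against 4257 ± 332 (log2 fold change 1.85 ± 1.03, adjusted p = 0.318).

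In the list of the epidermal differentiation complex 1 of 19 members rose, and 6 adjusted over the list alone. It was called upwards (camera adjusted p = 6.22e-04), but not with the correlation estimated (adjusted p = 0.169 with an estimated correlation). CRNN-EDC was at 6.05 CPM against 0.709 ± 0.374 (log2 fold change 3.09 ± 0.62, adjusted p = 0.0588), and SCFN-EDC had a log2 fold change of 1.82 ± 1.57 (adjusted p = 0.522). SCFN-EDC had 16 counts in the subconfluent library and 0, 11 and 1 in monolayers 1 to 3, and its log2 fold change was 1.17 without monolayer 1 and 4.41 without monolayer 2. The keratin list, without the Krt5L, Krt14L, Krt9L and Krt78L names, was called downwards (camera adjusted p = 0.0120). Over all features 0 of 10 members were past the threshold, and 3 fell adjusted over the list alone. The call did not hold with the correlation estimated (adjusted p = 0.117 with an estimated correlation). Krt20 and Krt19 had log2 fold changes of -4.06 ± 0.84 (adjusted p = 0.0634) and -2.09 ± 0.86 (adjusted p = 0.199), and Krt15 one of 0.86 ± 0.33 (adjusted p = 0.178). Without monolayer 1, CRNN-EDC and Krt20 were called (adjusted p = 0.0406 and 0.0480), and with DESeq2 both and Krt19 were called (adjusted p = 0.00992, 1.46e-04 and 0.0342). Camera also called the Krt9L, -EDC and CBP -K families upwards (adjusted p = 0.0308, 0.0172 and 0.0371), and each was lost with the correlation estimated (adjusted p = 0.846 with an estimated correlation). Without monolayer 1 the Krt9L and CBP -K calls were lost as well (adjusted p = 0.0961 for both). With the title mark wo as a term the calls of the keratin list and the -EDC family were lost (adjusted p = 0.0803 and 0.138).

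Of 15019 features, 91 rose and 109 fell, and 3520 had an unadjusted p under 0.05. The split moved with the scaling, to 39 rises and 83 falls with RLE size factors, 34 and 97 with total counts, and 680 and 1230 with DESeq2. With the title mark wo as a term, which only replicates 2 and 3 of the monolayers and skin equivalents carry, 676 rose and 575 fell. The number called was 683 without monolayer 1, 1 without monolayer 2 and 0 without monolayer 3, was 0 with only these groups in the fit, and was 1910 with DESeq2. With 1 subconfluent library there is no replicate check.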

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

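The tests on skin equivalent 2 were chosen, with their bounds, after the values had been seen, whereas the counts over other splits of the libraries were set before their results were seen, though the name families they use were defined from the data.

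Fragments given to no gene lie outside the comparisons, and several of their shares were above those of the confluent monolayers. The unmapped share was 6.11% ± 0.90 in skin equivalents, 9.22% in fibroblasts and 6.47% in subconfluent keratinocytes, against 4.19% ± 0.549 in monolayers. The multimapping share was 8.03% ± 0.854 in skin equivalents and 5.46% in subconfluent keratinocytes, against 4.53% ± 0.0752. The unassigned share was 13.7% in fibroblasts, against 21.0% ± 1.47 in monolayers. The ambiguous share was 0.755% ± 0.0860 in skin equivalents, 2.53% in fibroblasts and 0.635% in subconfluent keratinocytes, against 0.538% ± 0.0465.

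Between skin equivalents and confluent monolayers 6549 features changed, and among the 9 other splits of the 6 libraries into 3 and 3 the highest number was 0, so 1 of 10 splits gave as many. Of the fixed lists 2 changed, and the highest of the other splits also gave 2 (2 of 10 splits gave as many). Of the name families 5 changed, and the highest of the other splits gave 6 (5 of 10 splits gave as many). With 10 splits no share under 0.05 can be reached.

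Corneous beta-proteins ending in -S and -C held 0.967% of gene counts in skin equivalent 2, which was 11.2 times the highest other skin equivalent, and all 14 tested -C and all 10 tested -S features were highest in that library. A larger library or another scaling may raise counts, but the median log2 ratio of these features over the other skin equivalents lay 3.24 above that of all tested features. Fragments moved from near-identical -K and -F copies would lower those by what -S and -C gained, yet their share (1.45%, 1.95% and 2.21% in skin equivalents 1 to 3) was 1.07 times the mean of the others, above skin equivalent 1 and below skin equivalent 3 by 0.255 percentage points against a gain of 0.880. However, 9 of 15 tested -K features were also highest in skin equivalent 2, so the excess was not confined to -S and -C names. CBP37-K had 0.881, 482 and 9.48 CPM in skin equivalents 1 to 3, and CBP38-K 0.996, 522 and 9.55. Rises of such -K features could hide a loss in others, so an exchange of fragments is not excluded. Fragments lost to multimapping elsewhere would leave skin equivalent 2 with a lower multimapping share, which was higher by 0.288 percentage points. However, -S and -C gained only 0.608 and 0.575 percentage points of all fragments over skin equivalents 1 and 3. The multimapping shares of those libraries, 7.06% and 8.37%, differed from each other by more than that. Other differences could hide such a loss, so it is not excluded. Cells or RNA of another tissue and a difference between cultures were not tested and stay open.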

How the results depend on the processing

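Name families, shares, their alternatives and the fits with the title mark wo were chosen after the data were seen. For skin equivalents the number of features changed ranged from 5067 to 7502 (only libraries with wo), with leave-one-out values of 5067 to 6911, and 0 of the 6549 calls took the opposite sign in any alternative. Deviations of same-numbered libraries had correlations of -0.0433, -0.113 and 0.157, and monolayer 1 correlated best with skin equivalent 2 (0.176). With so few libraries per group these correlations cannot decide whether the numbers pair the samples, so pairing stays open. With the replicate block edgeR called 5991 and DESeq2 6707. Among the named features followed through the alternatives, the block with edgeR ended 1 call and added 1. With DESeq2 it ended 2 and added 3. For fibroblasts the number was 4608 to 7793 over the libraries left out. The causes of the changes below were not tested.

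For subconfluent keratinocytes, 200 features became 1910 with DESeq2, 348 with limma-voom, 1251 with wo as a term, 122 with RLE size factors, 131 with total counts, 0 with only these groups, 0 with the replicate block, and 0 to 683 over the monolayers left out. With the block CBP58-K had an adjusted p of 0.0819 and EDCH3-EDC of 0.0748.

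With an estimated correlation the lists called went from 2 to 0 in skin equivalents, 2 to 1 in fibroblasts and 2 to 0 in subconfluent cells, and the families from 5, 2 and 3 to 0 in each. With fry, fibroblasts had 1 list and 1 family and subconfluent cells 0 families. Without a filter fibroblasts had 5 families. Leaving out monolayers gave fibroblasts 1 to 2 lists and 1 to 2 families, and subconfluent cells 1 to 3 families. With the replicate block subconfluent cells had 1 list and 5 families, and with wo as a term 1 list.

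Signs reversed only in features that were not called, and ranges here are over single libraries left out. In skin equivalents Krt14L2 (0.21) became -0.062 with total counts and ranged from -0.080 (without monolayer 1) to 0.40. EDMPN1-EDC (-0.73) ranged from -2.50 to 0.68 (without monolayer 1), EDDM-EDC (0.47) from -0.062 (without skin equivalent 1) to 0.78, with -0.11 in only the libraries with wo, and CBP61-K (-0.01) from -1.03 to 0.52 (without monolayer 1), with 0.00282 without a filter, 0.025 with wo as a term and 0.95 in only the libraries with wo. In subconfluent cells EDQL-EDC (0.34) became -0.32 with the block, -0.29 with wo as a term and ranged from -0.038 (without monolayer 3) to 1.03. Krt8 (-0.06) became 0.071 with limma-voom, 0.31 with the block and 0.30 with wo, and ranged from -0.49 to 0.22 (without monolayer 2). Krt84L (-0.16) became 0.15 with limma-voom and ranged from -0.57 to 0.58 (without monolayer 1). IL36RN (0.25) became -0.37 with the block, -0.32 with wo and ranged from -0.30 (without monolayer 2) to 1.58. LOR3-EDC (0.94) became -0.13 with the block and -0.13 with wo. In fibroblasts the camera direction of the -C and -S families turned without monolayer 1 (adjusted p = 0.910 for both, range 0.713 to 0.910).

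Of the remaining alternatives of named features, 920 of those in skin equivalents, 387 in fibroblasts and 462 in subconfluent cells kept sign and side of the threshold. Calls absent from the main setting appeared in at least 1 alternative for 5, 6 and 18 named features, and calls were lost in at least 1 for 4, 5 and 2, in the same order.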

Other observations

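The features below and the tests on shared controls were chosen after the values had been seen.

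The skin equivalents differed by family and library. Of 27 tested -EDC features, 21 were highest in skin equivalent 1, with a median log2 ratio of 1.45 over the other skin equivalents, and their share of gene counts was 2.04%, 0.682% and 1.03% in skin equivalents 1, 2 and 3. For -K names the order differed, with 1.45%, 1.95% and 2.20% of gene counts. Keratins held 9.06%, 12.6% and 12.8%. In the monolayers, -EDC names held 0.0855%, 0.0492% and 0.0317% of gene counts and Krt78L names 0.00924%, 0.0603% and 0.0550%. Monolayers 2 and 3 were the closest pair of libraries, with a Spearman correlation of 0.994 across genes, which are not independent replicates, against 0.962 and 0.966 between monolayer 1 and monolayers 2 and 3. Monolayers 2 and 3 also share the title mark wo, which monolayer 1 lacks.

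Log2 ratios over the monolayers covaried between the subconfluent library and skin equivalents. A candidate explanation is a partly shared difference from confluent monolayers. Over 13230 features the covariance of the log2 ratios was 0.854. In 100 simulations in which the groups were unchanged and shared the same controls, its mean was 0.117 and its highest value 0.130. The correlation across features was 0.349, no higher than the simulated mean of 0.352. The same sign was held by 62.6% of features, against a simulated mean of 61.4% and a highest value of 62.5%. The simulations changed no group, so their correlation and sign share follow largely from how many libraries each ratio held. In the data 6549 of the 13230 features changed in skin equivalents. Correlation and sign therefore cannot tell how much of the agreement the shared controls gave. With different monolayers as the controls of each ratio, in all 6 ways, the covariance was 0.601 to 0.840. The shared controls alone do not give this covariance, although each way leaves 1 monolayer alone on one side. Of 91 features called higher in subconfluent cells 70 were called higher in skin equivalents, against 23.6 for independent lists, and of 109 called lower 69 were called lower, against 25.7. Independent lists leave out the shared controls, so part or all of the excess in these overlaps may come from them, and the subconfluent calls ranged from 0 to 1910 over the alternatives.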
